A study of Mus musculus with 6 samples.

How the data were processed

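Total mRNA of primary mouse brain microvascular endothelial cells was sequenced in 6 libraries, 3 from Krit1fl/fl and 3 from Krit1ECKO cells. Groups and replicate numbers were taken from the sample titles. The series' design text calls the replicates independent biological replicates and does not say whether libraries with the same number share animals or a preparation day.

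STAR and HOMER were used by the authors on the mm10 genome, per the submitters' processing notes, and their versions are not given in the sources used here. Per the file headers, the authors counted reads over the exons of RefSeq genes with HOMER, merged transcripts per gene with a minimum setting of 64, and compared the groups with HOMER's differential expression program. The statistical test inside that program and the strand setting are not given in the sources used here. In every gene of the deposited table the largest recovered count was at least 64, so genes of low expression are not analysed here. The deposited signal values are gene read counts multiplied by a factor per library: after division by that factor (0.831 to 1.17), 99.8% to 100% of the values of a library lay within 0.005 of a whole number. The header names no adjustment, yet the columns sum to nearly the same total. The library totals recovered in this way were 27417375, 32591613 and 26404953 reads in Krit1fl/fl replicates 1 to 3, and 25671872, 27044044 and 23133485 in Krit1ECKO replicates 1 to 3. A count of 3 reads corresponded to 0.092 to 0.130 CPM, and this floor covers counting error only. The authors' deposited table also holds a log2 fold change, a p-value and an adjusted p-value per gene. The sign of that log2 fold change was read from the values: it followed the log2 ratio of the Krit1ECKO to the Krit1fl/fl mean with a correlation of 0.9999 across genes, and was positive where Krit1ECKO was higher.

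Because the deposited values were scaled, the test planned for counts was replaced by the one planned for normalized values: limma (version 3.58.1 in R 4.3.3) with a mean-dependent prior variance, fitted to log2(value + 1) of all 6 libraries and all 11653 genes, without a further filter and without a block. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are ratios of geometric means, so they can differ from the ratio of the printed means. The test, the gene lists, the rule for named genes and most other settings were fixed before the data were examined. With 3 libraries per group an exact permutation test of a single gene cannot go below 0.1. The exact permutation test of Krit1, Klf2, Klf4 and Thbs1 used SciPy 1.17.1 with Python 3.11.15.

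A total of 34 gene lists were written from general knowledge, including markers of other cell types that the cultures could hold. The KLF2 and KLF4, ADAMTS, thrombospondin, BMP and endothelial-mesenchymal transition lists were chosen knowing published work on CCM genes. Lists with at least 5 measured members, 26 in number, were tested with camera at a preset correlation of 0.01 and adjusted together. Camera compares a list with all other genes for a shift in 1 direction, so members that move in opposite directions offset each other. Fry, used as an alternative, tests whether the members of a list move on balance in 1 direction and does not compare them with other genes.

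Named genes were chosen by a fixed rule. It took Krit1, Klf2, Klf4 and Thbs1, and the 12 largest increases and 12 largest decreases among genes that passed, had a mean log2 CPM of at least 1, showed no overlap between the groups and were not predicted or unnamed models. In each described list it took up to 4 passing members with the smallest adjusted p, or the 2 most expressed members where none passed. It also took the 2 most expressed members of each cell type list and the 5 most abundant genes. A few named genes and 1 gene list are not reported here. Of the 121 named genes, 9 share at least 20% of their exonic bases with another gene of the GENCODE vM21 annotation (GRCm38, the assembly of mm10): Dll1, Klk8, Lsr, Ctgf, Nrarp, Kif20a, Gabarapl1 and Ctsl with a gene on the opposite strand, and Ctsd with a gene on the same strand. Since the strand setting of the counting is not known, the values of these genes can include reads of the overlapping gene. Reads of genes with near-identical copies, such as ribosomal protein genes, Tmsb10 and Ly6a, could be split between copies, so their values are uncertain.

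The same replicate numbers occur in both groups. Deviations from the group means correlated across genes at 0.189, 0.524 and 0.359 for the libraries numbered 1, 2 and 3, each above the set minimum of 0.1, and every library correlated best with the library of its own number. The numbers therefore pair the libraries by that rule, a pairing read from the data and not stated in the labels, and a fit with the replicate number as a block was run as an alternative. Reads of replicate libraries differed by more than sampling noise in every pair within a group, so no library was counted as a repeat of another. Separate preparations from the same animals could also differ in this way, so this does not show that the replicates are biologically independent.

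The other settings fixed in advance were limma-voom on the recovered reads, median-of-ratios scaling, totals of the listed genes, quantile normalization, pseudocounts of 0.1 and 0.5, a filter of a value of at least 1 or of at least 1 CPM in 3 libraries, a minimum absolute log2 fold change of 1, the replicate block, leaving out each library in turn, and the authors' own comparison. Robust empirical Bayes, median-of-ratios scaling with the replicate block, library quality weights and leaving out both libraries numbered 2 were added after the data had been seen. The fit was tested on simulated data drawn from the means and totals of these libraries, with 200 of 11653 genes changed in each of 5 draws. For Krit1ECKO against Krit1fl/fl it called 97.6% of 250 genes lowered by a log2 change of 2, 83.2% of those lowered by 1, 84.4% of those raised by 1 and 96.0% of those raised by 2, and 4.34% of its calls were false. Camera called 10 of 10 raised simulated lists and 0 of 30 unchanged lists. The simulated genes were drawn independently of each other, so these lists cannot show how camera treats lists whose members vary together. Each simulated gene also had the same spread in both genotypes, whereas the real controls varied more than Krit1ECKO. The called and false shares may therefore differ in the real data.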

Results

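Primary brain microvascular endothelial cells, the cells that line the small vessels of the brain, were compared by RNA sequencing with and without deletion of Krit1, an adaptor protein of the cerebral cavernous malformation (CCM) complex. The 3 control libraries came from cells with floxed Krit1 and no Cre recombinase (Krit1fl/fl). The 3 deleted libraries came from cells that also carried a tamoxifen-inducible Cre recombinase under an endothelial Pdgfb promoter (Krit1ECKO). Cells of both genotypes received hydroxy-tamoxifen, so the drug does not separate the groups, whereas Cre itself does. The deposited values covered 11653 genes and corresponded to between 23133485 reads (Krit1ECKO replicate 3) and 32591613 reads (Krit1fl/fl replicate 2) per library. Values are scaled read counts as mean ± SD with n = 3 per genotype, and log2 fold changes of Krit1ECKO over Krit1fl/fl are given with their SE.

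The Krit1ECKO libraries resembled each other more than the controls did. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.990 to 0.993 within Krit1ECKO, 0.968 to 0.987 within Krit1fl/fl and 0.952 to 0.970 between the genotypes. The first principal component held 60.4% of the variance and separated the genotypes, and the second, with 23.0%, placed Krit1fl/fl replicate 1 at 31.9 and Krit1fl/fl replicate 2 at -23.5. Fn1, which encodes fibronectin and was the most abundant transcript, took 4.30% of the reads in Krit1fl/fl replicate 2 and 1.37% to 2.93% in the other libraries. The remaining 4 of the 5 most abundant genes, Col4a1, Col4a2, Sparc and Hspg2, encode basement membrane and matrix proteins. None of the 5 passed the test in limma, with adjusted p from 0.141 for Fn1 to 0.903 for Hspg2. Fn1 had a log2 fold change of -0.82 ± 0.33. It passed without Krit1fl/fl replicate 1 (adjusted p = 0.0162), with library quality weights (0.0137) and in the authors' deposited table (0.00262).

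Krit1 was lower in each of the 3 Krit1ECKO libraries. The gene (NR_033173) lies on chromosome 5 from 3803181 to 3844515 on the plus strand of mm10, and its value fell from 1654 ± 51.3 to 839.9 ± 51.8, a 1.97-fold decrease (log2 fold change -0.98 ± 0.07, limma adjusted p = 3.64e-04). The control libraries read 1646, 1607 and 1709, and the Krit1ECKO libraries 803.0, 817.5 and 899.1. The values count reads over all exons, so reads from exons outside the deleted part are included, and 50.8% of the control value was left. An exact two-sided permutation test gave p = 0.1, the smallest value possible with 3 libraries against 3.

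Klf2 and Klf4, zinc finger transcription factors induced in endothelium by laminar flow, rose strongly, and Thbs1, which encodes the angiogenesis inhibitor thrombospondin 1, fell. Klf2 (NM_008452, chromosome 8, 72319062 to 72321654, plus strand) rose 7.72-fold from 824.1 ± 491.6 to 5653 ± 232 (log2 fold change 2.95 ± 0.38, limma adjusted p = 0.00302). Klf4 (NM_010637, chromosome 4, 55527137 to 55532475, minus strand) rose 7.62-fold from 595.0 ± 285.9 to 4212 ± 231 (2.93 ± 0.30, adjusted p = 0.00135). Thbs1 (NM_011580, chromosome 2, 118111876 to 118127133, plus strand) fell 4.64-fold from 189800 ± 118800 to 38010 ± 15510 (-2.21 ± 0.46, adjusted p = 0.0173). The spread of Thbs1 came mainly from the controls, with 97537, 323881 and 147906 in replicates 1 to 3, against 34090, 55100 and 24836 in Krit1ECKO. The Thbs1 call was lost without Krit1fl/fl replicate 3 (adjusted p = 0.0542), Krit1ECKO replicate 1 (0.0741) or Krit1ECKO replicate 3 (0.0566). The exact two-sided permutation p was 0.1 for each of the 3 genes, again the smallest possible.

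**Figure D1:**
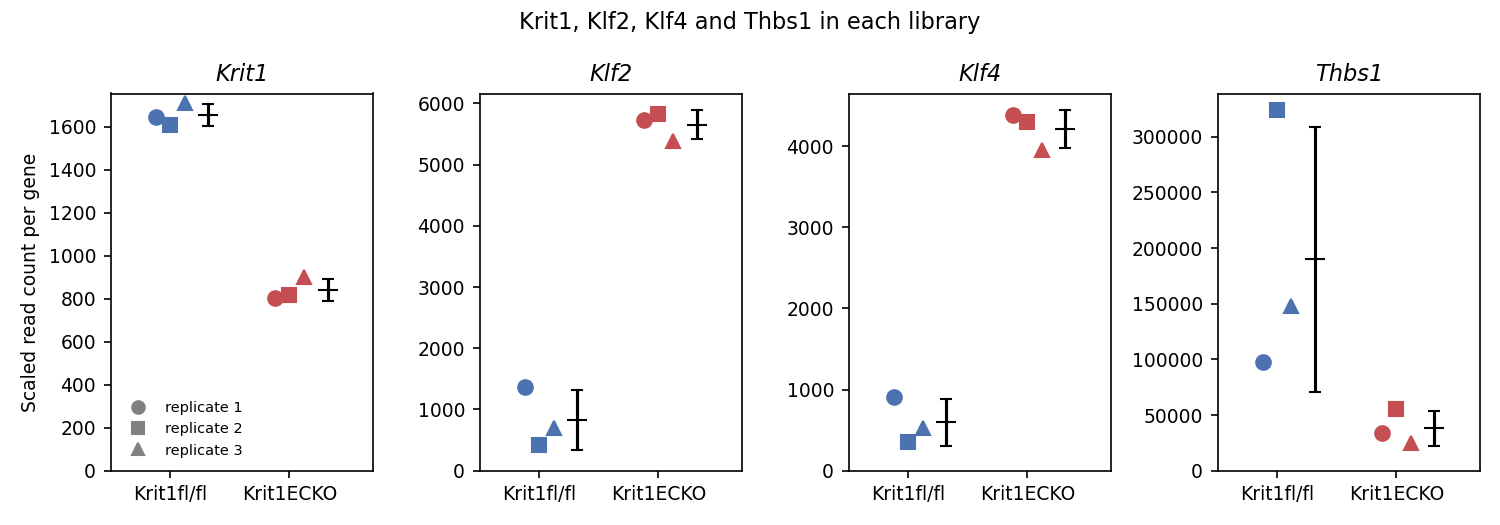
Scaled read counts (linear axis from 0) of Krit1, Klf2, Klf4 and Thbs1 in each of the 3 Krit1fl/fl and 3 Krit1ECKO libraries, with the replicate number as the symbol. The dash and bar beside each group are the mean and SD (n = 3), and the control libraries of Thbs1 spread from 97537 to 323881.

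Across all genes, 2166 of 11653 differed between the genotypes in limma at an adjusted p below 0.05, of which 1455 were higher and 711 lower in Krit1ECKO. With an absolute log2 fold change of at least 1 in addition, 494 genes remained, 325 higher and 169 lower. The groups did not overlap for 4352 genes (37.3%), where chance gives 10% with 3 libraries against 3, and 2162 of the changed genes were among them. The share of higher genes was 67.2%, and with quantile normalization it was 52.8%, with 1190 higher and 1062 lower. The count was 1205 without Krit1fl/fl replicate 3, 901 without Krit1ECKO replicate 1 and 1087 without Krit1ECKO replicate 2. Without both libraries numbered 2, of which the Krit1fl/fl one held almost no reads of Y-linked genes, it was 985.

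Esr1, which encodes oestrogen receptor alpha, showed the largest increase among the named genes, from 29.7 ± 6.3 to 3524 ± 277 (116-fold, log2 fold change 6.86 ± 0.15, limma adjusted p = 4.06e-06). The Krit1ECKO cells alone carry a Cre recombinase fused to an oestrogen receptor domain, and the values do not separate reads of that transgene from reads of Esr1. The next largest increases were those of the tyrosine phosphatase gene Ptprr (26.6-fold), the synaptotagmin gene Syt7 (23.0-fold), the fibroblast growth factor receptor gene Fgfr3 (21.1-fold), the taurine transporter gene Slc6a6 (20.1-fold) and the Notch ligand gene Dll1 (18.2-fold). Lrg1, which encodes a leucine-rich glycoprotein, rose 17.0-fold. Mgp, which encodes the BMP-binding matrix Gla protein, rose 16.6-fold, and Eln, which encodes elastin, rose 16.4-fold. Klk8, Fndc1 and the carbonic anhydrase gene Car4 rose 16.4-fold, 12.8-fold and 12.2-fold. Mgp was the most abundant of these in Krit1ECKO, at 14310 ± 6574 against 842.9 ± 304.3 in controls.

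The largest decrease among the named genes was that of Dgkk, a diacylglycerol kinase gene, which fell from 743.8 ± 371.3 to 53.0 ± 15.9 (12.98-fold, log2 fold change -3.70 ± 0.38, limma adjusted p = 0.00132). Myl9, which encodes a myosin light chain, was 9.06-fold lower (-3.18 ± 0.72, adjusted p = 0.0234), with control values of 624.3, 4779 and 1891. That call was lost without Krit1fl/fl replicate 3 (0.0795), Krit1ECKO replicate 1 (0.0599), Krit1ECKO replicate 2 (0.0655) or Krit1ECKO replicate 3 (0.0721), with limma-voom (0.0666), and without both libraries numbered 2 (0.0803). Lonrf2 fell 9.05-fold, the chloride channel gene Cftr 8.05-fold and the transporter genes Abca9 and Slc35f1 7.30-fold and 6.40-fold. Bmp2, which encodes a bone morphogenetic protein, fell 5.89-fold from 1087 ± 193 to 185.4 ± 47.1. Gpx3, F2rl2 and Col27a1 fell between 5.21-fold and 5.57-fold, and the adjusted p of these 9 genes other than Myl9 lay between 2.47e-04 and 0.0079.

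**Figure D2:**
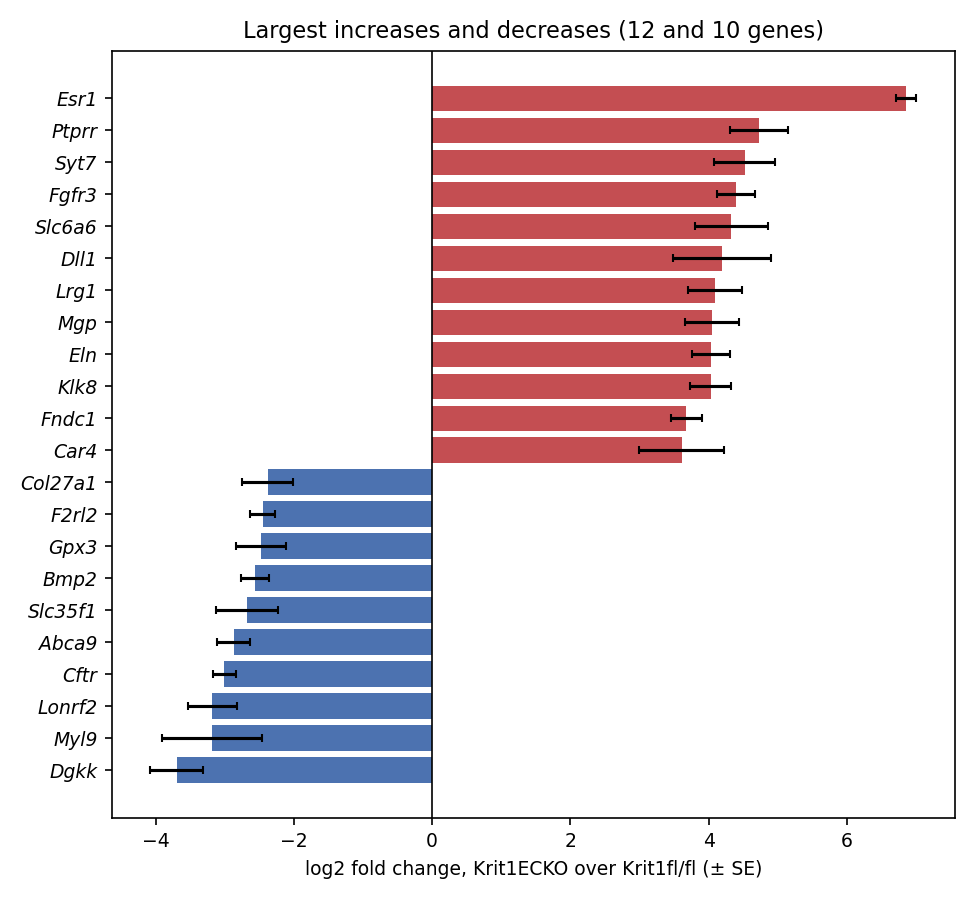
Log2 fold change of Krit1ECKO over Krit1fl/fl (bars, with SE, 3 libraries per genotype) for the 12 genes with the largest increase and for 10 of the 12 with the largest decrease chosen by the fixed rule. Esr1 stands at 6.86, and the other increases lie between 3.61 and 4.73.

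Among 10 measured genes of the CCM complex and its partners, 2 were higher, Krit1 was lower and 7 did not pass. Adjusted over the list alone, 3 were higher and 1 lower. Over the other fits, which changed the scaling, filter, model or set of libraries, 1 to 4 were higher and 1 to 3 lower. Ccm2l, a paralogue of Ccm2, rose 2.03-fold (log2 fold change 1.02 ± 0.13, limma adjusted p = 0.00326), and Heg1, which encodes the transmembrane partner of Krit1, rose 1.54-fold (0.62 ± 0.12, adjusted p = 0.0132). The Heg1 call was lost without Krit1fl/fl replicate 3 (0.059), Krit1ECKO replicate 1 (0.0613) or Krit1ECKO replicate 2 (0.0543). The list as a whole did not pass (camera adjusted p = 0.969).

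Klf2, Klf4 and their endothelial targets moved in both directions, with 9 of 18 measured members higher, 4 lower and 5 not passing (10 and 4 adjusted over the list alone). The other fits gave 6 to 12 higher and 4 lower. Podxl, which encodes the sialomucin podocalyxin, rose 5.12-fold to 55950 ± 6278 (limma adjusted p = 5.69e-04). Slc9a3r2, which encodes a scaffold protein, rose 3.14-fold (adjusted p = 2.47e-04). Edn1, which encodes the vasoconstrictor endothelin 1 and is repressed by Klf2, fell 2.27-fold from 28000 ± 584 to 12350 ± 1055 (adjusted p = 3.52e-04). As a list they did not pass (camera adjusted p = 0.0814) and did with the replicate number as a block (0.0374), with median-of-ratios scaling (0.0256), without Krit1fl/fl replicate 1 (0.00627) or without Krit1fl/fl replicate 2 (0.0327). The camera adjusted p was 0.852 with an estimated correlation.

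Of 11 thrombospondins and other endogenous angiogenesis inhibitors, 2 were higher, 5 lower and 4 not passing, and the counts adjusted over the list alone were the same. The semaphorin gene Sema3f and the metalloproteinase inhibitor gene Timp2 rose 2.99-fold and 2.68-fold (limma adjusted p = 0.00142 and 0.00423), while Sema3a fell 2.65-fold (0.00495), as Thbs1 did. The list did not pass (camera adjusted p = 0.443). Without Krit1fl/fl replicate 3 or Krit1ECKO replicate 1, 1 member was lower, without Krit1ECKO replicate 3 there were 2, and without Krit1fl/fl replicate 2 or Krit1ECKO replicate 2 there were 3. Over all other fits 1 to 6 were lower. Among 10 ADAMTS proteases, which include cleaving enzymes of matrix proteoglycans, Adamts10 was 1.60-fold higher (adjusted p = 0.00636) and 9 did not pass, also adjusted over the list alone (camera adjusted p = 0.513). The higher members numbered 3 without Krit1fl/fl replicate 1, 2 without Krit1fl/fl replicate 2 and 4 with library quality weights.

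VEGF signalling and tip cell genes split, with 6 of 22 higher, 7 lower and 9 not passing (6 and 9 adjusted over the list alone, camera adjusted p = 0.2). Plvap, which encodes the diaphragm protein of fenestrated endothelium, rose 7.30-fold from 1275 ± 364 to 9492 ± 3342 (limma adjusted p = 0.00134). Aplnr, the apelin receptor gene, rose 10.2-fold from 11.7 ± 6.7 to 120.0 ± 19.7 (0.00246). Angpt2, which encodes the Tie2 ligand angiopoietin 2, fell 2.78-fold from 111100 ± 17000 to 40060 ± 6648 (0.00192), and Igfbp3 fell 3.40-fold (0.00214). The higher members numbered 2 or 3 without any single library other than Krit1fl/fl replicate 1, and the lower members 3 without Krit1ECKO replicate 1 and 4 without Krit1ECKO replicate 3. Library quality weights gave 7 higher and 11 lower.

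Among pan-endothelial identity genes, none passed as lower, with 5 of 22 higher, 0 lower and 17 not passing (5 and 0 adjusted over the list alone, camera adjusted p = 0.596). Vwf, which encodes von Willebrand factor, rose 2.52-fold to 66300 ± 17590 (limma adjusted p = 0.00935), Mmrn2 1.80-fold (0.00532), Icam2 1.44-fold (0.0115) and the angiopoietin receptor gene Tek 1.97-fold (0.0177). The Vwf call was lost without both libraries numbered 2 (0.0747), the Icam2 call without Krit1ECKO replicate 1 (0.0561), and the Tek call without Krit1fl/fl replicate 3 (0.0664) or any of Krit1ECKO replicates 1 (0.0776), 2 (0.0517) and 3 (0.0533), or without both libraries numbered 2 (0.0534). The number of higher members fell to 2 without Krit1ECKO replicate 1 and to 3 without Krit1fl/fl replicate 3, Krit1ECKO replicate 2 or Krit1ECKO replicate 3. None passed as lower in most other fits, but 4 did with library quality weights, 3 with median-of-ratios scaling and the replicate block, and 1 with the block alone or without Krit1ECKO replicate 2.

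Blood-brain barrier and tight junction genes gave 4 higher, 3 lower and 21 not passing of 28 (4 and 6 adjusted over the list alone, camera adjusted p = 0.596). Lsr, a tricellular junction gene, rose 4.03-fold (limma adjusted p = 0.00147), the lipid transporter gene Mfsd2a 4.70-fold from 32.4 ± 7.5 (0.0015), and the glucose transporter gene Slc2a1 1.96-fold to 40900 ± 5999 (0.00367). The transcription factor gene Foxf2 fell 1.54-fold (0.00457). The lower members numbered 5 without Krit1fl/fl replicate 2, with median-of-ratios scaling or with quantile normalization, 7 in the authors' deposited table and 9 with library quality weights. The replicate block gave 6 higher and 5 lower.

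Venous and lymphatic endothelial genes gave 6 higher, 2 lower and 5 not passing of 13 (7 and 2 adjusted over the list alone), and arterial genes 1 higher, 2 lower and 9 not passing of 12 (2 and 5 adjusted over the list alone, camera adjusted p = 0.828). Ephb4, an ephrin receptor gene of veins, rose 2.01-fold (limma adjusted p = 6.98e-04), and Nr2f2, which encodes the venous transcription factor COUP-TFII, rose 1.94-fold (0.00221). Tmsb10 fell 1.55-fold (0.00267). The venous and lymphatic list did not pass (camera adjusted p = 0.0739) and did with the replicate number as a block (0.019), with median-of-ratios scaling (0.0273), with fry (0.0239), without Krit1fl/fl replicate 1 (0.0457) or without Krit1ECKO replicate 3 (0.0391). Its adjusted p was 0.808 with an estimated correlation. Of the arterial members other than Mgp, Unc5b fell 1.68-fold (0.0207) and Nrp1 fell 1.33-fold (0.0488). The Unc5b call was lost without Krit1ECKO replicate 1 (0.0873), 2 (0.0576) or 3 (0.0504). The Nrp1 call was lost without any single library other than Krit1fl/fl replicate 2 (0.067 to 0.153), with limma-voom (0.0522), with scaling to the totals of the listed genes (0.0527), and without both libraries numbered 2 (0.0736). Arterial members numbered 5 higher and 2 lower without Krit1fl/fl replicate 1, 1 and 5 without Krit1fl/fl replicate 2, and 1 and 0 without any 1 of the Krit1ECKO libraries. They numbered 1 and 4 with median-of-ratios scaling or quantile normalization, 3 and 3 with the replicate block, and 5 and 5 with library quality weights. Venous and lymphatic members ranged from 3 to 9 higher and from 1 to 3 lower over the other fits.

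Of 13 markers of endothelial-mesenchymal transition, 1 was higher, 0 lower and 12 not passing (also adjusted over the list alone, camera adjusted p = 0.596). The higher one, Ly6a, also known as Sca-1, rose 2.90-fold from 27290 ± 2566 to 78940 ± 6733 (limma adjusted p = 3.83e-04). There were 5 higher and 1 lower without Krit1fl/fl replicate 1, and 7 and 2 with library quality weights. Krit1fl/fl replicate 1 had a sum of measured fibroblast and meningeal markers of 6243, against 559.4 and 352.0 in Krit1fl/fl replicates 2 and 3. The counts of this list thus depend on that control, and the cause was not tested. Notch signalling genes gave 3 higher, 1 lower and 9 not passing of 13 (5 and 4 adjusted over the list alone, camera adjusted p = 0.707). Lfng, which encodes a glycosyltransferase acting on Notch receptors, rose 8.26-fold from 239.4 ± 2.4 to 2049 ± 593 (3.46e-04), beside Dll1, whose control values were 193.5, 19.1 and 55.4. Nrarp rose 1.90-fold (0.0307), a call lost without Krit1fl/fl replicate 3 (0.0911) or any of Krit1ECKO replicates 1 (0.0741), 2 (0.103) and 3 (0.0846), or without both libraries numbered 2 (0.0892), where its log2 fold change of 0.92 became 0.60. Rbpj fell 1.28-fold (0.0191), a call lost without Krit1ECKO replicate 1 (0.0811) or 3 (0.0632) or both libraries numbered 2 (0.0607). The Notch list gave 5 higher and 2 lower without Krit1fl/fl replicate 1, 4 and 4 without Krit1fl/fl replicate 2, 2 and 0 without Krit1ECKO replicate 1 or 3, and 3 and 3 with median-of-ratios scaling or quantile normalization.

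BMP and TGF-beta signalling genes fell as a group, with 11 of 22 lower, 2 higher and 9 not passing (11 and 4 adjusted over the list alone, camera adjusted p = 0.00505). The camera adjusted p was 0.504 with an estimated correlation, which was -0.007 for this list. Besides Bmp2, Bmp6 fell 1.86-fold from 7817 ± 563 to 4228 ± 604 (limma adjusted p = 0.00287). Ctgf and Cyr61, which encode matricellular proteins and are also known targets of the YAP coactivator, fell 2.37-fold and 2.54-fold (0.00147 and 0.00333), with Ctgf at 80320 ± 5191 in the controls. Without Krit1fl/fl replicate 1, 4 members were higher, and the other fits gave 1 to 6 higher and 9 to 12 lower.

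Coagulation and fibrinolysis genes rose as a group, with 9 of 19 higher, 1 lower and 9 not passing, and the same counts adjusted over the list alone (camera adjusted p = 0.00579). The camera adjusted p was 0.808 with an estimated correlation. Plaur, the urokinase receptor gene, rose 2.65-fold from 1699 ± 52 to 4496 ± 135 (limma adjusted p = 1.54e-04), S100a10, which encodes a plasminogen receptor subunit, 2.42-fold (3.52e-04), and Entpd1, which encodes an ectonucleotidase that degrades ATP and ADP, 3.80-fold (0.0015). The thrombin receptor gene F2r fell 2.92-fold from 12170 ± 969 to 4190 ± 628 (5.69e-04). Without Krit1fl/fl replicate 1, 3 members were lower, and the other fits gave 7 to 10 higher and 1 to 3 lower.

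Proliferation genes rose together, with 25 of 30 higher, 0 lower and 5 not passing (29 and 0 adjusted over the list alone, camera adjusted p = 2.6e-11). The camera adjusted p was 0.808 with an estimated correlation, which was 0.736 for this list, and fry gave 0.0523. The changes were modest: the mitotic checkpoint gene Bub1b rose 1.67-fold from 816.1 ± 99.0 to 1356 ± 104 (limma adjusted p = 0.00449), the replication licensing genes Mcm4 and Mcm7 rose 1.67-fold and 1.66-fold (0.00504 and 0.00638), and the kinesin gene Kif20a rose 1.60-fold (0.00796). The number of higher members was 7 without Krit1ECKO replicate 1, 11 without Krit1ECKO replicate 2 and 5 without both libraries numbered 2, and no member was lower in these fits. The Kif20a call was lost without both libraries numbered 2 (0.0539).

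Unfolded protein response genes passed as a list in the lower direction (camera adjusted p = 0.00233), although most members moved little. Of 20 members 0 were higher, 5 lower and 15 not passing, with the same counts adjusted over the list alone. Their median log2 fold change was -0.08, and -0.18 to -0.05 over the other fits. The camera adjusted p was 0.808 with an estimated correlation, and fry gave 0.0523. Chac1, which encodes a glutathione-degrading enzyme, fell 2.36-fold (limma adjusted p = 0.00315), the asparagine synthetase gene Asns 1.87-fold (0.00692), the stress transcription factor gene Atf3 1.58-fold (0.00442) and the pseudokinase gene Trib3 1.52-fold (0.00824). Over the other fits 4 to 8 members were lower and 0 higher.

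Basement membrane and matrix genes gave 6 higher, 6 lower and 20 not passing of 32 (7 and 7 adjusted over the list alone, camera adjusted p = 0.596). The laminin chains moved apart: Lamb1 fell 3.40-fold from 20940 ± 1018 to 6179 ± 634 (limma adjusted p = 2.47e-04), while Lamb2 rose 1.67-fold from 13680 ± 986 to 22840 ± 1106 (0.0015). Col15a1 fell 3.48-fold (0.00201), and Eln was the largest increase of the list. The matrix list gave 13 higher and 8 lower without Krit1fl/fl replicate 1, 13 and 10 with library quality weights, and 3 and 4 without both libraries numbered 2. Endothelial inflammation genes gave 4 higher, 1 lower and 15 not passing of 20 (6 and 1 adjusted over the list alone, camera adjusted p = 0.763). The leukocyte adhesion genes Icam1 and Selp rose 2.00-fold and 6.88-fold (9.11e-04 and 0.00195). Cd14 rose 2.34-fold (0.0445) and Tlr4 fell 1.22-fold (0.0232), and both calls were lost without Krit1fl/fl replicate 3 or without any of the 3 Krit1ECKO libraries (0.0792 to 0.137 for Cd14, 0.0518 to 0.0926 for Tlr4). The Cd14 call was also lost with robust empirical Bayes (0.0628), and the Tlr4 call without both libraries numbered 2 (0.0755). The inflammation list gave 6 higher and 3 lower without Krit1fl/fl replicate 1, 7 and 4 with the replicate block, and 2 and 0 without Krit1fl/fl replicate 3, Krit1ECKO replicate 1 or Krit1ECKO replicate 3.

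**Figure D3:**
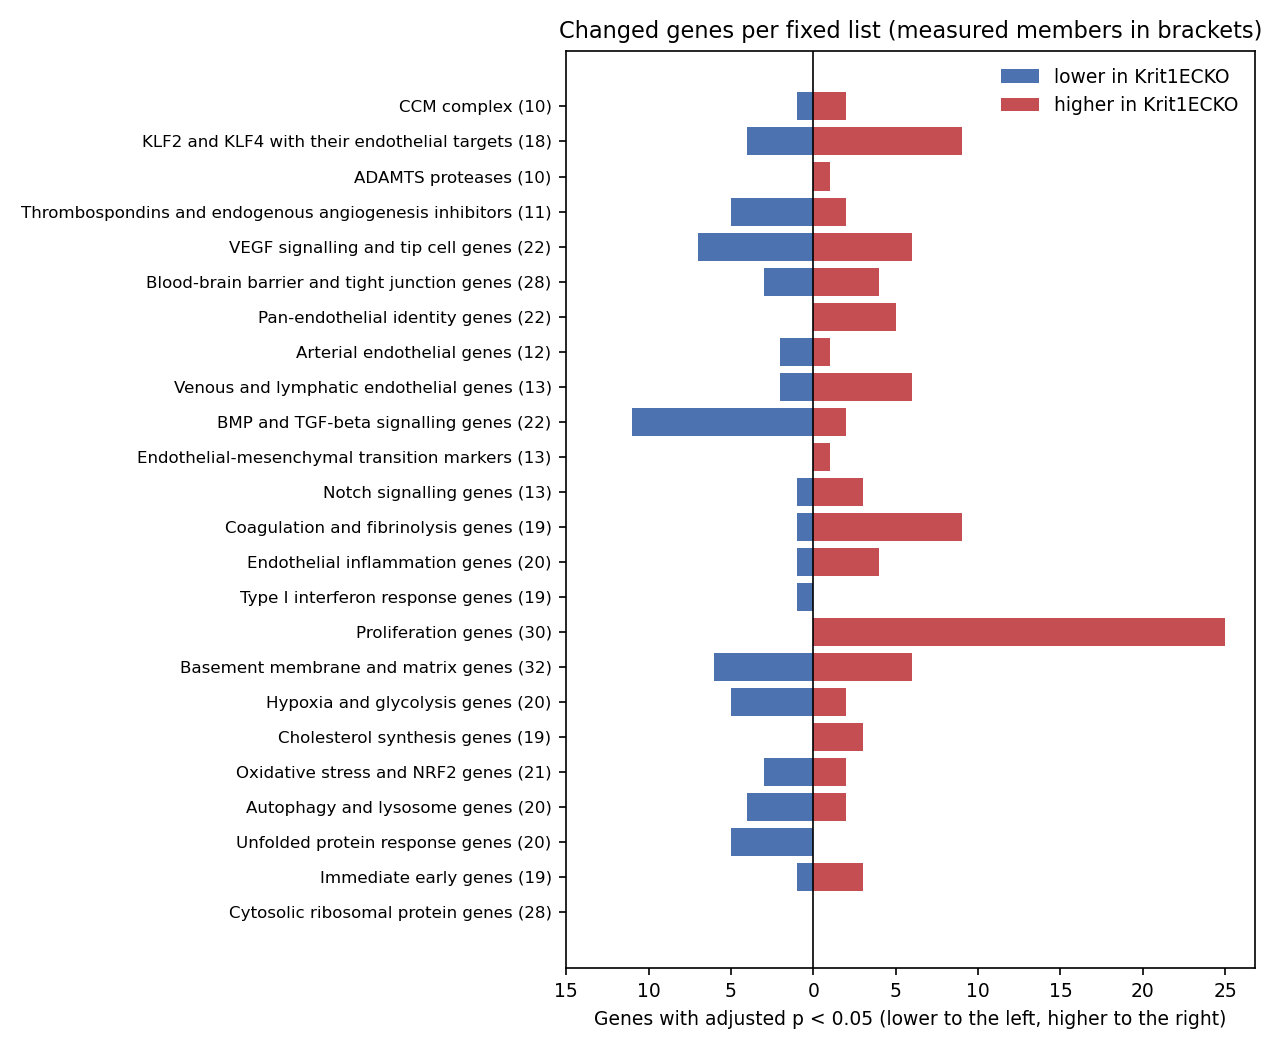
Number of measured genes per described list with an adjusted p below 0.05 in limma, lower in Krit1ECKO to the left and higher to the right, with the number of measured members in brackets. Proliferation genes show 25 higher and 0 lower, and BMP and TGF-beta signalling genes 2 higher and 11 lower.

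For 7 lists that did not pass, camera leaned lower while the median log2 fold change was above 0: the CCM complex (0.05), blood-brain barrier genes (0.02), arterial genes (0.13), matrix genes (0.18), and the hypoxia (0.03), oxidative stress (0.02) and type I interferon (0.001) lists given in the last part. The medians of all of these other than the arterial list fell below 0 in at least 1 other fit.

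Markers of other brain cell types were mostly not among the measured genes. Of the fibroblast and meningeal markers 6 of 14 were measured, with 1 lower and 5 not passing, and Col1a2 and Col1a1 varied mainly among the controls, with 2745, 192.9 and 61.6 for Col1a2 and 1990, 96.4 and 23.6 for Col1a1 in Krit1fl/fl replicates 1 to 3 (limma adjusted p = 0.535 and 0.584). Without Krit1fl/fl replicate 1 they passed as higher in Krit1ECKO (0.0125 and 0.0106), and the list gave 4 higher and 0 lower with a median log2 fold change of 2.64 in place of 1.08. That median was 0.49 without Krit1fl/fl replicate 2 and 0.04 without Krit1fl/fl replicate 3. It was -0.42 in the authors' deposited table, whose log2 fold changes followed ratios of arithmetic and not geometric means. With library quality weights the list gave 4 higher and 1 lower, with Col1a2 at 0.0227 and Col1a1 at 0.0249. The 1 lower call was lost without any single library, without both libraries numbered 2 and with the replicate block. Of the pericyte and smooth muscle markers 3 of 16 were measured and none passed, with Anpep at 71.5 ± 76.3 and 75.0 ± 27.8 (0.666) and Cspg4 at 91.1 ± 138.4 and 72.8 ± 39.0 (0.623) in controls and Krit1ECKO. Without Krit1fl/fl replicate 1 both passed as higher (0.0399 and 0.019), as Cspg4 did with library quality weights (0.0361). Microglia and macrophage markers gave 1 lower and 2 not passing of 3. Laptm5 had 1213 ± 110 and 1069 ± 183 (0.364), and Mrc1 fell 2.62-fold (0.0331), a call lost without any single library other than Krit1fl/fl replicate 2 (0.0614 to 0.11), with limma-voom (0.0532), and without both libraries numbered 2 (0.0574).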

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

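Robust empirical Bayes, library quality weights, median-of-ratios scaling with the replicate block, and leaving out both libraries numbered 2 were chosen after the data had been seen. Krit1 kept its direction in every setting run, and its call in all but the minimum absolute log2 fold change of 1, which its -0.98 does not reach. Of 106 named genes that passed, 82 passed in each of the 6 fits that left out a single library, 24 did not in at least 1, and none reversed in any setting. Most named genes were chosen from these data for large changes or small adjusted p, so their share overstates stability. Of all 2166 changed genes, 893 passed again without Krit1ECKO replicate 1, the fewest, and 1859 without Krit1fl/fl replicate 1, the most. Another scaling ended the calls of 4 (Cyp51, Idi1, Gja1 and Nrp1). No gene shared between the 2166 and another setting had the opposite sign. All settings reuse the same 6 libraries, and 2162 of the 2166 genes had no overlap between the groups. A reversal could therefore hardly occur, and its absence is no independent support. The median log2 fold change of all genes moved between -0.04 and 0.05.

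Leaving out a single library gave 901 to 2297 changed genes, 610 to 1575 higher and 291 to 730 lower, with fewer libraries in each fit. A minimum absolute log2 fold change of 1 gave 494, 325 and 169, by construction. Without both libraries numbered 2 there were 985, 622 and 363. Library quality weights gave 4256, 2490 and 1766, with a weight of 6.67 for Krit1fl/fl replicate 3 and 0.40 to 1.09 for the other libraries, and raised the number of passing members in most lists. Median-of-ratios scaling with the replicate block gave 1115 lower genes and a share of higher genes of 56.3%. The causes of these shifts were not tested. The remaining settings gave 2063 changed genes (limma-voom) to 2549 (median-of-ratios scaling with the replicate block), and the replicate block alone 2529. The authors' deposited table calls 2058 genes, 1205 higher and 853 lower, of which 1738 are among the 2166.

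Camera with an estimated correlation called 0 of the 26 lists (1 at an unadjusted p below 0.05). The preset correlation called 5 and fry called 3. The estimated correlation of the BMP and TGF-beta list, -0.007, lay below the preset 0.01. A higher correlation therefore does not account for the lost call of that list. What ended the calls was not otherwise tested. The replicate block ended the calls of Cyp51 and Idi1, and gave calls for Enpp2, Stmn2, Rplp0 and the lists of KLF2 and KLF4 with their targets and of venous and lymphatic genes. It changed no other call of a named gene or list. DESeq2, edgeR with its TMM scaling and its low-count filter were planned for counts and were not run. The plan named limma for files that hold only normalized values, and the deposited values are scaled. Scaling alone did not prevent a count test, since limma-voom was run on the recovered reads. With 3 libraries per genotype at this depth, 83.2% to 97.6% of simulated changes of 1 or 2 log2 units were called, and genes under 64 reads in each library are not analysed here.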

Other observations

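The tests in this part that weigh explanations were chosen after the results had been seen. Several stress and metabolic groups had members that moved without the list as a whole passing in camera. Hypoxia and glycolysis genes gave 2 higher, 5 lower and 13 not passing of 20 (3 and 5 adjusted over the list alone, camera adjusted p = 0.434), and 1 to 3 higher and 3 to 6 lower over the other fits. The vasodilator peptide gene Adm fell 2.73-fold, and the glycolytic genes Pfkp and Pfkfb3 fell 1.66-fold and 2.02-fold (limma adjusted p = 0.00289, 0.00125 and 0.00504). Oxidative stress genes gave 2 higher, 3 lower and 16 not passing of 21 (the same adjusted over the list alone, 0.596): Nqo1, a target of NRF2, rose 4.54-fold (0.00101), the extracellular antioxidant enzyme genes Gpx3 and Sod3 fell 5.57-fold and 2.72-fold (0.00469 and 0.00473), and Srxn1 rose 1.30-fold (0.0178), a call lost without Krit1ECKO replicate 1 (0.0753) or 2 (0.0694) or both libraries numbered 2 (0.0772). The other fits gave 1 to 3 higher and 2 to 5 lower members of this list. Of 20 autophagy and lysosome genes 2 were higher, 4 lower and 14 not passing (the same adjusted over the list alone, 0.596). Ctsd, the cathepsin D gene, rose 2.25-fold to 57960 ± 7769 (0.00125). Ctsl, Gabarapl1 and Atg7 changed by -0.66, -0.55 and 0.39 on the log2 scale (0.0144, 0.0233 and 0.0267). Those 3 calls were lost without Krit1fl/fl replicate 3, Krit1ECKO replicate 1 or Krit1ECKO replicate 2, and for Gabarapl1 and Atg7 also without Krit1ECKO replicate 3 (0.0571 to 0.103), and for Atg7 without Krit1fl/fl replicate 2 (0.0549) or both libraries numbered 2 (0.13). The number of lower members was 0 without Krit1fl/fl replicate 3, Krit1ECKO replicate 1 or Krit1ECKO replicate 2, and 1 without Krit1ECKO replicate 3.

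Cholesterol synthesis genes gave 3 higher, 0 lower and 16 not passing of 19 (the same adjusted over the list alone, camera adjusted p = 0.434). Of these, Idi1 and Cyp51 rose 1.56-fold and 1.19-fold (limma adjusted p = 0.0369 and 0.039), and both calls were lost without any single library other than Krit1fl/fl replicate 2 (0.0624 to 0.12) and with the replicate block (0.0508 and 0.0532), quantile normalization (0.0961 and 0.119) or both libraries numbered 2 left out (0.133 and 0.0836), and in the authors' deposited table (0.12 and 0.309). The Cyp51 call was also lost with median-of-ratios scaling (0.0914). Over the other fits 0 to 4 cholesterol synthesis genes were higher and 0 to 2 lower. Immediate early genes gave 3 higher, 1 lower and 15 not passing of 19 (4 and 1 adjusted over the list alone, 0.707), with Fosb 2.42-fold, Dusp1 1.38-fold and Nr4a1 2.52-fold higher (0.00476, 0.00493 and 0.0112). The Nr4a1 call was lost without Krit1ECKO replicate 1 (0.0557). The immediate early list gave 6 higher without Krit1fl/fl replicate 1 or with the replicate block, and 2 to 7 higher and 1 to 3 lower over the other fits. Of 19 type I interferon response genes 0 were higher, 1 lower and 18 not passing (0 and 0 adjusted over the list alone, 0.596), and Bst2, the lower one, had an adjusted p of 0.0343, which was 0.0737 to 0.117 without Krit1fl/fl replicates 2 or 3 or Krit1ECKO replicates 1 or 3, and 0.0609 without both libraries numbered 2. None of 28 cytosolic ribosomal protein genes passed in limma, also adjusted over the list alone or in limma-voom (camera adjusted p = 0.434), 3 were higher at an unadjusted p below 0.05, with Rpl4 at 0.176 and Rplp0 at 0.0918, and Rplp0 passed with the replicate block (0.0289) and without Krit1fl/fl replicate 1 (0.0493).

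Few markers of other cell types were measured. Of 4 astrocyte markers 2 were higher, Fgfr3 and Gja1 (1.54-fold, limma adjusted p = 0.0491, lost without any single library other than Krit1fl/fl replicate 1, at 0.0641 to 0.162, with limma-voom at 0.054, with scaling to the totals of the listed genes at 0.0558 with robust empirical Bayes at 0.0567 and without both libraries numbered 2 at 0.0961). Of 2 neuron markers Tubb3 rose 2.46-fold (0.0015), and Stmn2 had 66.1 ± 81.5 and 298.7 ± 62.4 (0.0527), which passed with the replicate block (0.0301), with limma-voom (0.0271), in the authors' deposited table (0.0074) and without Krit1fl/fl replicate 1 (0.00101). Of 2 oligodendrocyte markers Cnp rose 1.35-fold (0.0177), a call lost without Krit1ECKO replicate 1 (0.0659) or 2 (0.0673) or both libraries numbered 2 (0.0794), and Cspg4 did not pass. Of 3 ependymal and choroid plexus markers Clic6 fell 1.68-fold (0.00539) and Enpp2 had 5233 ± 2586 and 2600 ± 799 (0.173), which passed with the replicate block (0.0426), in the authors' deposited table (0.00318), without Krit1fl/fl replicate 2 (0.0156) and without both libraries numbered 2 (0.0382). Among red blood cell genes, Bpgm had 322.0 ± 52.4 and 336.5 ± 33.9 (0.781). No T cell, B cell or granulocyte marker was measured.

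Of the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 2166 changed genes in limma, and the highest of the others gave 0, including the other splits that part all 3 pairs. At an unadjusted p below 0.05 the real split gave 3739 genes and the highest of the others 1173. Each of the other splits puts libraries of both genotypes in each group, so a genotype difference widens the spread within the groups. Their low counts therefore do not measure what chance alone would give. With 10 splits a share below 0.05 cannot be reached.

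The rise of Esr1 was found in each Krit1ECKO library, at 3299 to 3833 against 25.6 to 36.9 in the controls. A change of its whole chromosomal neighbourhood was argued against by the 11 measured genes within 1 Mb, whose median log2 change was 0.17 and of which 0 passed in limma. Reads of the transgene, whose Cre recombinase is fused to an oestrogen receptor domain and which the controls lack, may account for the rise. The lowest Krit1ECKO value was 89.3 times the highest control value, and the Krit1ECKO values lay within 1.16-fold of each other. Such evenness does not favour a transgene, since Dll1 (1086 to 1127) and Klf2 (5390 to 5831) were also even among the Krit1ECKO libraries. Cre and Krit1 deletion occur in the same libraries and the values are per gene, so transgene reads and a rise of Esr1 itself cannot be told apart.

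Krit1 fell to 50.8% of its control value. If the remainder came from undeleted cells with the control profile, no gene should fall further than Krit1, yet 38 genes did so with 95% intervals that lay below that of Krit1 (-1.14 to -0.82), which argues against that account. Reads from exons outside the deleted part may remain in deleted cells, and the 50.8% cannot be told apart by exon in values summed per gene. Apart from undeleted cells, no biological explanation of the remainder was tested.

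Thbs1 was highest in Krit1fl/fl replicate 2, at 323881, or 2.64 times the mean of the other controls. Depth or scaling was argued against by a ratio of 2.81 after median-of-ratios scaling. Fibroblasts or mural cells stay open, since the values go both ways: the sum of their 9 measured markers was 617.6, 0.092 times the 6711 of Krit1fl/fl replicate 1, where Thbs1 was lowest, but above the 398.1 of Krit1fl/fl replicate 3. Myl9, which smooth muscle also expresses, was highest in replicate 2 (4779, against 624.3 and 1891 in replicates 1 and 3). That library also had a sum of 4.15 over the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y against 3376 and 2775 in the other controls, and an Xist value of 36539 against 18732 and 19269. Krit1ECKO replicate 2 likewise had the lowest Y-linked sum of its group (1066) and the highest Thbs1 (55100), so the sex of the animals, such cells or another property of the preparations numbered 2 may contribute, and with 1 such pair these cannot be told apart.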
